A study of Homo sapiens with 18 samples.

How the data were processed

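Total RNA of ovarian carcinoma samples of 6 patients was hybridised to Affymetrix U95Av2 arrays, 3 arrays for each patient, as the sample titles record. The title of each sample gives the patient and the replicate number, and these were taken as group and replicate. The labels do not say whether the RNA came from tissue or from cultured cells, so the word tumour stands for the samples of 1 patient. The values used were the deposited intensities of the series' value table, 1 linear intensity per probe set and array, which can fall below 0. The software, background correction and scaling behind the deposited intensities are not given in the sources used here. Array medians between 133.8 and 149.3 units point to some scaling, which could shrink or create differences between arrays that cannot now be undone. No detection call was used, so a reading above the floor does not by itself show that a gene was expressed, and levels of different probe sets were not set against each other.

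The table held 12625 probe sets. The platform annotation gave 10961 of them 1 gene, 545 several genes and 1119 none, and only those with 1 gene were used. Gene symbols were updated through Entrez numbers in a RefSeq gene table, which matched 10949. Removed before any test were 142 probe sets of sex-linked, immune receptor and other genes whose signal follows inherited variation. Where a gene had several probe sets (1900 genes), the brightest on average was used, and for named genes with another probe set that correlated with it at under 0.5 over the tumour means, that correlation is given. Quantile normalization (limma) was the main setting by a rule fixed before the data were examined, because the log2 array medians spanned 0.158. Values below the 5th percentile of positive values, 12.4 units, were set to it, and log2 was taken. Quantile normalization forces the same distribution on every array, so a shift of most genes in 1 tumour would not be seen.

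Genes were compared among the 6 tumours with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes with trend), by a moderated F-test and by contrasts for the 15 pairs, with Benjamini-Hochberg adjustment and a threshold of 0.05. A size of at least 2-fold, 1 log2 unit between the highest and the lowest tumour mean, was asked for as well in the counts so described. All p-values printed with a single gene are adjusted p-values of limma's tests. A fold was taken from tumour means of log2 values, and intensities are printed as mean ± SD of 3 arrays. Where the lowest tumour had an array below the 20th percentile of positive values, 42.9 units, the fold was computed with all values raised to that level. It is printed as a lower bound (at least) where all 3 arrays of that tumour lay below the level and as approximate (about) where 1 or 2 did, and where leaving out 1 array moved such a fold by more than 1.5 times, the log2 range is printed with its lowest and highest value instead. The share of variance between tumours came from the one-way variance components. Before the data were examined, 24 gene lists with 467 genes were fixed, of which 376 were measured. The score of a list on an array was the mean of its members' log2 values minus their means over the 18 arrays, tested by 100000 random assignments of arrays to tumours (permutation test of the F statistic, adjusted over the 24 lists). If only 1 tumour stands apart, random assignment keeps its 3 arrays together with a chance of 0.00735, which limits the p such a pattern can reach. Spread and coherence of the lists were set against 10000 random lists matched on mean expression in 20 bins. Correlations of list scores over the 6 tumour means used all 720 pairings, two-sided, where the smallest possible p is 0.00278. Scores by replicate number were tested by exact enumeration of the numbers within tumours.

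Genes were named by a rule fixed in advance. It took the 20 genes with the largest range among those that passed, whose highest tumour was above the median of all genes and whose replicates did not overlap between the highest and the lowest tumour; up to 4 members of each list with the smallest adjusted p; the 10 genes with the smallest range in the top quartile by mean; and set genes of platinum handling and repair. Genes named by replicate number and in the lists added later were chosen after the values were seen, as were DES, MSLN and WT1 of the mesothelial list. The F-test was tested on simulated data with the means and spreads of the 8129 genes, 200 of them changed in 1 tumour, in 20 draws. It recovered 77.0% of genes changed by 1 log2 unit and 97.4% of those changed by 2, and on average 4.62% of its calls were false. The simulated noise was normal and independent between genes and arrays, with no floor and no difference by replicate number. These shares may therefore not hold for the real arrays. A first version with 1 draw and unmoderated spreads gave a higher false share and was replaced. Alternatives were values as deposited, median centring, floors at the 1st and 20th percentile, only genes above the median by mean, the mean of all probe sets of a gene, eBayes without trend or robust, replicate number as a block, and each array left out in turn. Leaving out the arrays numbered 3 or a whole tumour, and the comparison of replicate numbers, were added after the data were examined. No array was left out of the main results. No carboplatin response was compared, because no label used here gives it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.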

Results

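Total RNA of ovarian carcinoma samples from 6 patients was measured on 18 Affymetrix U95Av2 oligonucleotide arrays, 3 replicate arrays for each patient. The samples of 1 patient are called a tumour here. The title of the series names sensitivity to carboplatin, a platinum drug that forms DNA adducts, as its subject. The sample labels used here give the patient and the replicate number but no carboplatin class, so no sensitive group could be set against a resistant group. The comparison that the labels allow is among the 6 tumours, measured against the spread of their replicates. The arrays held 12625 probe sets, and 8129 genes entered the tests. The median intensity of an array as deposited lay between 133.8 and 149.3 units, and 0.903% to 1.65% of an array's values were at or below 0. The number of arrays limits the precision of each value. The labels do not say whether the replicates of a tumour came from separate samples, cultures or RNA preparations, so the p-values measure the spread between these arrays only, which may be technical.

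The 6 tumours differed in the expression of most genes. Of the 8129 genes, 5771 (71.0%) differed among tumours by limma's moderated F-test with Benjamini-Hochberg adjustment, and 3341 (41.1%) also had at least a 2-fold distance between the highest and the lowest tumour mean. The distance reached 4-fold in 1241 genes and 16-fold in 322 genes. Between 2 tumours, a median of 1189 genes differed at least 2-fold, with a range of 200 to 1786 over the 15 pairs of tumours. The median share of a gene's variance that lay between tumours was 66.9%. Across genes, arrays of 1 tumour correlated with a median Pearson r of 0.973 (SD 0.010, range 0.963 to 0.993, 18 pairs of arrays), and arrays of different tumours with a median of 0.862 (SD 0.044, range 0.773 to 0.967, 135 pairs). Genes are not independent replicates, so these correlations describe the arrays and carry no test. The arrays with replicate number 3 stood apart from those with numbers 1 and 2 in all tumours (last part of the results), and without these 6 arrays the median share of variance between tumours was 86.2%. The 3 arrays of a tumour thus did not lie equally far apart. Fits without the arrays numbered 3, here and below, measure tumours only against the spread between numbers 1 and 2. Between these, 0 genes differed by limma.

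**Figure D1:**
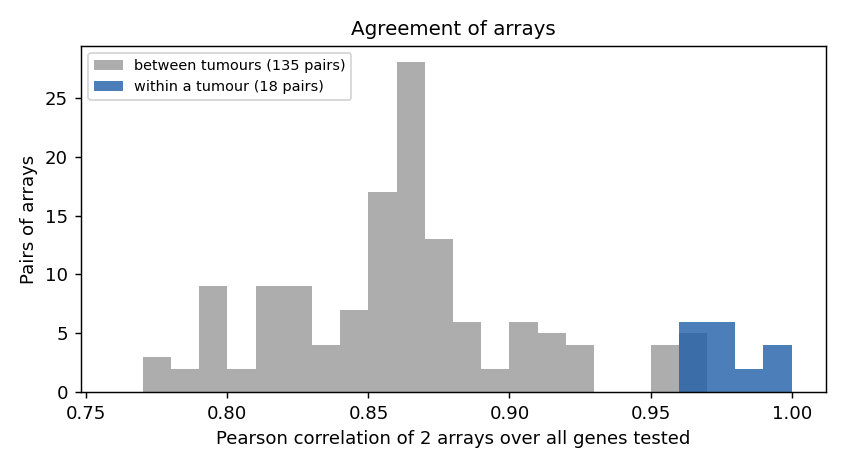
Pearson correlation of log2 intensity over the 8129 genes for each pair of the 18 arrays (x axis) against the number of pairs (y axis), in blue for pairs of arrays of 1 tumour and in grey for pairs of arrays of different tumours. The 18 pairs within a tumour lay between 0.963 and 0.993, and the 135 pairs between tumours lay between 0.773 and 0.967.

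The 20 genes with the largest distance between tumours were chosen by a rule fixed in advance. SPP1, which codes for the secreted phosphoprotein osteopontin, was at the floor of 12.4 units in the lowest tumour and at 5096 ± 305 units (SD, n = 3) in the highest. Because low intensities are uncertain, folds of genes whose lowest tumour had an array below 42.9 units were computed with that level as the smallest value. They are lower bounds (at least) where all 3 arrays of that tumour lay below it and approximate (about) where only some did. The bound for SPP1 was at least 119-fold. SPARC, a matrix glycoprotein, differed at least 132-fold, and ACTA2, smooth muscle actin, at least 118-fold. Among epithelial genes, the bound was at least 106-fold for the keratin gene KRT19, at least 57.5-fold for the tight junction gene CLDN4, at least 43.6-fold for CLDN3 and at least 42.7-fold for EPCAM, which codes for an epithelial adhesion molecule. CLDN4, CLDN3 and EPCAM each stayed below 42.9 units on all arrays of 3 tumours. LDHB, a subunit of lactate dehydrogenase, read 3170 ± 112 units in the highest tumour and lay below 42.9 units throughout in 2 tumours (at least 73.8-fold). MMP7, a matrix-degrading protease, differed at least 66.2-fold, S100P at least 72.2-fold, the cytokine gene IL6 at least 61.3-fold, the ubiquitin hydrolase gene UCHL1 at least 54.7-fold and NNMT, nicotinamide N-methyltransferase, at least 46.9-fold. The contractile genes MYL9 and CNN1 were below 42.9 units throughout in 5 and 4 tumours and reached 1819 ± 224 and 1717 ± 20.2 units in the highest. EMP3, NPPB, SRGN and BMP7 had bounds from at least 39.1-fold (BMP7) to at least 65.8-fold (EMP3). VIM (vimentin) read 76.2 ± 107 units in the lowest tumour, where 2 of 3 arrays lay below 42.9 units, and 5995 ± 95.1 in the highest, and its log2 range of 7.45 ran from 6.92 to 8.72 with 1 array left out. The adjusted p of the 20 genes lay between 4.56e-18 (CLDN4) and 0.000308 (IL6).

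**Figure D2:**
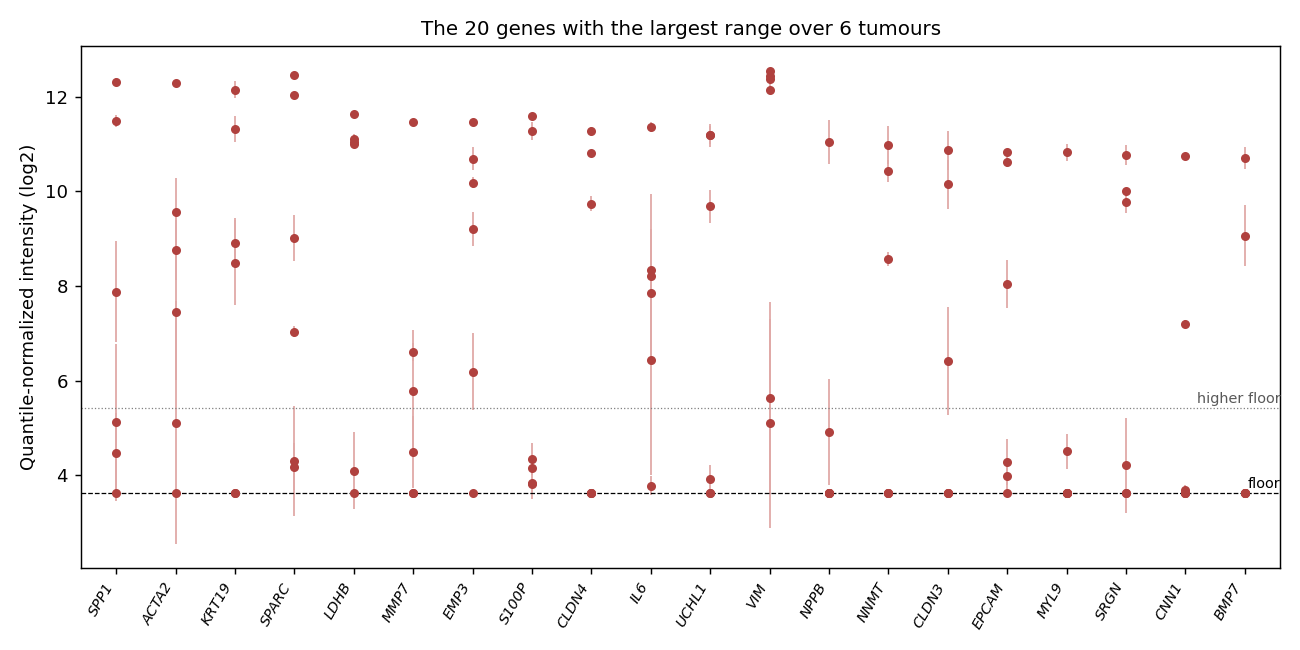
Tumour means of log2 quantile-normalized intensity (y axis) of the 20 genes with the largest range (x axis, in order of range), 6 points per gene, with error bars of 1 SD over 3 arrays. The dashed line is the floor of 12.4 units, the dotted line is the level of 42.9 units used for lower bounds, and CNN1 lies below the dotted line in 4 tumours.

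Markers of ovarian epithelium differed widely. Of 22 measured epithelial genes, 21 differed among tumours and 16 did so at least 2-fold. KRT18 ran from 109 ± 20.2 units in the lowest tumour to 7221 ± 288 in the highest (66.9-fold, adjusted p = 4.25e-12), and KRT8 from 315 ± 37.1 to 7768 ± 425 (24.8-fold, adjusted p = 1.48e-11). The mean list score, in log2 units relative to the mean of all arrays, ran from -1.84 ± 0.062 to 1.27 ± 0.125 (SD, n = 3), a range of 3.11. Fibroblast and matrix genes had the widest score range of the 24 lists, 4.32 log2 units, with 4 tumours between -1.60 and -0.43 and the other 2 at 1.73 and 2.72. Of 23 members, 21 differed and 19 did so at least 2-fold. FAP, the fibroblast activation protein, was below 42.9 units throughout in 4 tumours and reached 909 ± 142 units, at least 21.0-fold. The collagen genes COL5A2 and COL6A2 differed 23.6-fold and 15.9-fold, and THY1, a fibroblast surface protein, 8.83-fold. Members of this list moved together over the tumours, with a mean pairwise correlation of 0.72 against a median of -0.01 over 10000 random lists of like expression. Both scores passed a permutation test of the 18 arrays (adjusted p = 3.43e-05, from the smallest p of 1e-05 that 100000 permutations can give).

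Leukocyte, endothelial, erythroid and adipocyte markers spanned smaller score ranges, from 0.164 to 0.507 log2 units. Of 20 leukocyte genes, 7 differed and 1 did so at least 2-fold, namely CD68, a lysosomal protein of macrophages, which peaked at 123 ± 20.6 units (at least 2.84-fold, adjusted p = 5.84e-09). CSF1R, a macrophage receptor, and CD2, a T-cell adhesion protein, each differed 1.79-fold. The leukocyte score spanned 0.165 log2 units, which did not pass the permutation test (adjusted p = 0.133; 0.0296 with values as deposited and 0.0386 with the mean of all probe sets of a gene). Of 9 endothelial genes, ENG (2.12-fold) and CLDN5 (2.24-fold) differed, and the score spanned 0.243 log2 units (permutation test, adjusted p = 0.0527). That call depended on the setting, with adjusted p between 2.56e-05 and 0.0235 under 5 of the processing alternatives, and it also passed without tumour 5 replicate 3 (0.00573), tumour 5 replicate 2 (0.0293), tumour 2 replicate 1 (0.0447) or tumour 1 replicate 2 (0.0469), and without tumour 5 (0.00655). The erythroid score spanned 0.164 log2 units (permutation test, adjusted p = 0.388), with 3 of 4 members differing by less than 2-fold. Of 5 adipocyte genes, FABP4, a fatty acid carrier, passed the test but lay below 42.9 units throughout in all 6 tumours. The adipocyte score passed the permutation test (range 0.507, adjusted p = 0.00565), but not with the floor at the 1st percentile (0.13) or at the 20th (0.125), without the arrays numbered 3 (0.061) or with tumour 1 left out (0.149). All 7 measured mesothelial genes differed, 5 of them at least 2-fold, with a score range of 1.89 log2 units (permutation test, adjusted p = 3.43e-05). CALD1, an actin-binding protein of contractile cells, differed at least 39.8-fold and CALB2, the calcium-binding protein calretinin, 2.81-fold. DES differed at least 3.51-fold, and PDPN 4.66-fold by a probe set with which another correlated at -0.89. KRT5 lay below 42.9 units throughout in 5 tumours and differed only at least 1.21-fold by that level. MSLN differed 1.27-fold and WT1 1.31-fold, with another probe set of WT1 correlating at -0.12. The score may therefore rest largely on CALD1 and DES, and does not by itself show a difference in mesothelial cells.

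**Figure D3:**
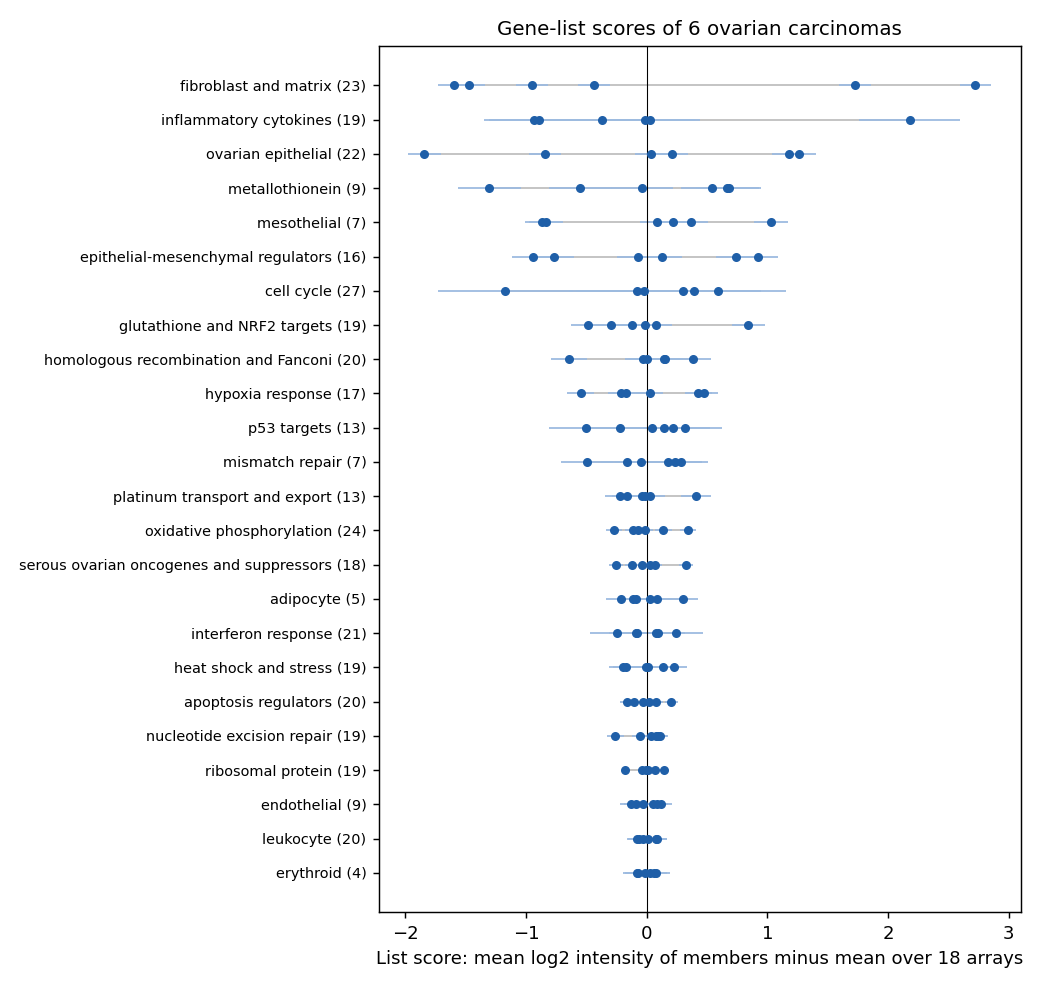
List scores (x axis, mean log2 intensity of the members minus their mean over the 18 arrays) of the 24 gene lists (y axis, number of measured members in parentheses), 1 point per tumour mean, with error bars of 1 pooled replicate SD. Fibroblast and matrix genes span 4.32 log2 units, epithelial genes 3.11 and leukocyte genes 0.165.

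Genes that handle platinum and thiols differed among tumours to very different degrees. Of 13 genes of platinum transport and export, 10 differed and 6 did so at least 2-fold. ABCC2, an efflux pump for conjugated drugs, was below 42.9 units throughout in 5 tumours and read 360 ± 13.4 units in the other, at least 8.37-fold higher (adjusted p = 1.42e-16). ABCC3, a related pump, had a log2 range of 4.69 (4.23 to 5.34 with 1 array left out, 2.79 with the mean of all probe sets). SLC31A1, the copper transporter that carries platinum drugs into cells, differed 1.48-fold (201 ± 10.6 to 297 ± 5.72 units, adjusted p = 0.000111). The copper-exporting ATPase ATP7B read 50.7 ± 6.87 to 67.7 ± 13.6 units and did not pass the test (adjusted p = 0.407). ATP7A, 1 of the 6 counted at 2-fold, lay below 42.9 units throughout in 4 tumours and differed only at least 1.10-fold by that level. The median SD of the 13 genes between tumours was 0.344, higher than in 53.9% of random lists of like expression, so their spread did not stand out. The platinum transport score spanned 0.627 log2 units (permutation test, adjusted p = 0.00202). With 1 of the tumours left out it spanned 0.246 (adjusted p = 0.166). All 9 metallothionein genes, which code for cysteine-rich metal-binding proteins, differed, 8 of them at least 2-fold, with a score range of 1.99 log2 units. MT1E differed 11.8-fold, MT1B 9.36-fold and MT1F 5.40-fold. Their probe sets are of a type shared within this family of near-identical genes, so the signal cannot be assigned to 1 member. Of 19 glutathione and NRF2 target genes, 18 differed and 17 did so at least 2-fold. GSTP1, a glutathione transferase, read 48.4 ± 9.96 units in the lowest tumour and 3357 ± 206 in the highest (about 68.8-fold, adjusted p = 1.88e-10). GPX2, a glutathione peroxidase, ran from 65.2 ± 4.69 to 690 ± 88.8 units and PGD, an enzyme of the pentose phosphate pathway, 2.96-fold. ME1 differed at least 22.3-fold by its brightest probe set, with which another probe set of the gene correlated at 0.08 over the tumour means.

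DNA repair genes also differed among tumours, where 71.0% of all genes tested differed and 41.1% did so at least 2-fold. In nucleotide excision repair, which removes platinum adducts, 17 of 19 genes differed and 8 did so at least 2-fold, with a score range of 0.367 log2 units (permutation test, adjusted p = 0.000609). ERCC1, part of the nuclease that cuts beside an adduct, ran from 259 ± 36.9 to 624 ± 41.7 units (2.42-fold, adjusted p = 5.68e-08). The replication protein A genes RPA3 and RPA1 differed 5.87-fold and 2.26-fold, and XPA, a damage-binding protein, 1.58-fold, with a second probe set of XPA correlating at -0.19. Of 20 homologous recombination and Fanconi genes, 13 differed and 8 did so at least 2-fold (score range 1.03, permutation test, adjusted p = 0.000609). RAD51C, a recombinase paralogue, ran from 92.2 ± 8.49 to 1165 ± 19.1 units (12.7-fold, adjusted p = 5.96e-10). NBN, part of the complex that senses double-strand breaks, differed 3.79-fold, BRCA1 2.75-fold and the checkpoint kinase gene ATR 2.06-fold. Of 7 mismatch repair genes, 6 differed and 4 did so at least 2-fold (score range 0.782, permutation test, adjusted p = 0.00925). RFC1, a clamp loader subunit, differed 2.18-fold and MLH3 2.26-fold. PCNA, the sliding clamp, differed 2.04-fold (adjusted p = 0.0237, and 0.0725 with median centring). With tumour 1 left out, none of these 3 scores passed the permutation test (adjusted p = 0.0758, 0.0588 and 0.17). On the arrays numbered 3, the mismatch repair score was lower than on those numbered 1 by 0.302 and the recombination score by 0.223, in 6 of 6 tumours each. The median SD of the members between tumours was set against random lists of like expression. It was higher than in 49.0% of them for excision repair, 66.9% for recombination and 72.3% for mismatch repair, so none of the 3 spreads stood out.

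Cell cycle genes differed among tumours and between replicates. Of 27 genes, 24 differed among tumours and 20 did so at least 2-fold, with a score range of 1.76 log2 units (permutation test, adjusted p = 0.0274). TYMS, thymidylate synthase, ran from 567 ± 123 to 2085 ± 308 units (3.71-fold, adjusted p = 8.04e-07), and the log2 range was 2.91 for TOP2A, topoisomerase II alpha (2.29 to 3.22 with 1 array left out), and 3.90 for CCNB2, a mitotic cyclin (3.05 to 4.50). BIRC5, survivin, differed 1.96-fold by a probe set with which another correlated at -0.39. The score of the arrays numbered 3 lay below that of the arrays numbered 1 by 0.824 log2 units and below those numbered 2 by 0.788, in 6 of 6 tumours. The call of the list was lost without tumour 1 replicate 3 (adjusted p = 0.11), tumour 4 replicate 1 (0.058) or tumour 4 replicate 2 (0.0556). With the whole of tumour 1 left out, the range fell to 0.676 (permutation test, adjusted p = 0.37), and with another tumour left out to 1.56 (0.0589). Without the arrays numbered 3, all 27 genes differed and the score range was 1.37 (permutation test, adjusted p = 0.00135). Of 13 p53 target genes, 12 differed and 10 did so at least 2-fold. The phosphatase gene PPM1D differed 11.6-fold (171 ± 16 to 1996 ± 364 units), the cell cycle inhibitor gene CDKN1A 10.9-fold and the death receptor gene TNFRSF10B 3.15-fold. Their score did not pass the permutation test (range 0.813, adjusted p = 0.0716). It passed with the mean of all probe sets (0.0298), without tumour 1 replicate 3 (0.0415), without tumour 6 replicate 3 (0.0233), without all arrays numbered 3 (0.00372), and with 1 or another whole tumour left out (0.0485 and 0.0471). Of 20 apoptosis regulators, 17 differed and 11 did so at least 2-fold. CFLAR, an inhibitor of caspase 8, differed 7.25-fold, PMAIP1, a p53-induced BH3 protein, 5.50-fold and BID 3.20-fold, while the score spanned 0.368 log2 units (permutation test, adjusted p = 4.8e-05).

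The inflammatory cytokine score stood apart in 1 tumour. Of 19 genes, 15 differed and 14 did so at least 2-fold. IL1B ran from 98.9 ± 9.56 to 5479 ± 330 units (55.5-fold, adjusted p = 2.28e-14). CXCL6, a neutrophil-attracting chemokine, was below 42.9 units throughout in 5 tumours and read 1276 ± 156 units in the other (at least 29.6-fold). TNFAIP2 differed 11.9-fold and CCL20 at least 2.65-fold. The score spanned 3.11 log2 units (permutation test, adjusted p = 0.00106), with 5 tumours between -0.93 and 0.03 and the other at 2.18. Without that tumour, tumour 1, the range was 0.962 (permutation test, adjusted p = 0.118). On the arrays numbered 3 the score was lower than on the arrays numbered 1 by 0.622 in 6 of 6 tumours. Of 21 interferon response genes, 15 differed and 13 did so at least 2-fold, among them IFI27 (at least 26.4-fold), the immunoproteasome gene PSMB9 (6.16-fold) and ISG20 (4.08-fold). The interferon score did not pass the permutation test (range 0.488, adjusted p = 0.207), and passed it without the arrays numbered 3 (0.00426), on which it was higher than on the arrays numbered 1 by 0.352 in 6 of 6 tumours. Of 19 heat shock and stress genes, 15 differed and 9 did so at least 2-fold (score range 0.427, permutation test, adjusted p = 0.00226). IER3 differed 28.5-fold, the phosphatase gene DUSP1 at least 36.9-fold, ZFP36, which destabilizes cytokine transcripts, 7.89-fold and DNAJB1 2.54-fold. The members' median SD between tumours was higher than in only 25.3% of random lists of like expression, so the largest of these folds do not stand for the list.

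All 17 hypoxia response genes differed, 10 of them at least 2-fold (score range 1.02, permutation test, adjusted p = 4.8e-05). The carbonic anhydrase gene CA12 ran from 36.5 ± 2.79 to 2654 ± 647 units (at least 60.7-fold), LOX, a collagen cross-linking enzyme, differed about 45.5-fold, the prolyl hydroxylase gene P4HA2 8.45-fold and VEGFA, an angiogenic growth factor, 4.78-fold. Of 16 regulators and markers of epithelial-mesenchymal transition, 15 differed and 12 did so at least 2-fold (score range 1.87, permutation test, adjusted p = 3.43e-05). CDH2, N-cadherin, ran from 105 ± 19.8 to 2852 ± 266 units (27.3-fold, adjusted p = 2.76e-12) and FN1, fibronectin, differed 14.3-fold. TWIST1, a transcription factor of mesenchymal cells, lay below 42.9 units throughout in 4 tumours and differed at least 5.61-fold. Of 18 oncogenes and suppressors of serous ovarian carcinoma, 15 differed and 12 did so at least 2-fold (score range 0.578, permutation test, adjusted p = 4.8e-05). NOTCH3 differed at least 24.2-fold, the cell cycle inhibitor gene CDKN2A at least 8.58-fold, PAX8, a transcription factor of Müllerian epithelium, 4.36-fold and AKT1 3.55-fold.

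Ribosomal protein genes differed little but reproducibly. All 19 passed the test and none reached 2-fold, with RPL30 at 1.63-fold, RPL8 at 1.61-fold and RPS3 at 1.43-fold. The score spanned 0.321 log2 units against a pooled replicate SD of 0.026 (permutation test, adjusted p = 3.43e-05). The median SD of the members between tumours was 0.169, against 0.298 in random lists of like expression. Of 24 oxidative phosphorylation genes, 23 differed and 13 did so at least 2-fold, among them NDUFS3 (3.01-fold), SDHA (2.27-fold) and NDUFV1 (2.13-fold), with a score range of 0.614 (permutation test, adjusted p = 3.43e-05). Over the 24 lists fixed before the data were examined, the number of genes that passed adjusted over the list alone was the number over all genes tested, except in the leukocyte list, where it was 6 and not 7. Among brightly read genes with the smallest range, NPHP4 differed 1.05-fold (adjusted p = 0.926), GATA4 1.06-fold (0.97) and DSTN, an actin-depolymerizing factor, 1.11-fold (0.858). The range of GAPDH was 0 because its probe set was the brightest gene probe set on each array, which quantile normalization sets to 1 value, and it was 0.20 log2 units with values as deposited (adjusted p = 0.26) and 0.366 with the mean of all its probe sets (adjusted p = 0.000319).

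Scores of 8 pairs of lists were compared over the 6 tumour means, and none passed the exact permutation test after adjustment. The epithelial score tended to be lower where the matrix score was higher (Pearson r = -0.88, exact p = 0.0222, adjusted p = 0.063, and Spearman rho = -0.94, exact p = 0.0167, adjusted p = 0.0667). Without the 2 tumours farthest from the median of the epithelial score, r was -0.90. That leaves only 4 tumours and does not remove both tumours with high matrix scores. Below, the matrix score set the median for matrix with leukocyte. The epithelial score did so for epithelial with leukocyte, and the cell cycle score for cell cycle with recombination. The leukocyte score tended to be higher with the matrix score (r = 0.93, exact p = 0.0125, adjusted p = 0.063; rho = 0.89, exact p = 0.0333, adjusted p = 0.0889; r = 0.69 without 2 tumours) and lower with the epithelial score (r = -0.87, exact p = 0.0236, adjusted p = 0.063; rho = -0.94, exact p = 0.0167, adjusted p = 0.0667; r = -0.73 without 2 tumours), although its own range of 0.165 did not pass. A single leukocyte gene, CD68, had a range of 3.27 log2 units, and the next largest in that list was 0.842 (CSF1R). The correlations of the leukocyte score may therefore rest largely on CD68. With the median of the members in place of their mean, r was -0.78 for epithelial with matrix scores and 0.73 for matrix with leukocyte scores. It was only -0.19 for epithelial with leukocyte scores (exact permutation, adjusted p = 0.196, 0.196 and 0.787). Because 4 tumours lay between -1.60 and -0.43 in the matrix score and the other 2 lay at 1.73 and 2.72, its correlations rest in part on this split, and neither set is large enough for a test of its own. Cell cycle and recombination scores gave r = 0.87 (exact p = 0.0583, adjusted p = 0.117; rho = 0.54, exact p = 0.297, adjusted p = 0.474), which fell to 0.31 without 2 tumours and so rests on them.

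Arrays that carried the replicate number 3 differed from those numbered 1 and 2, a comparison added after the data were examined. With the tumour as a term of the limma fit, 1618 genes differed between numbers 3 and 1 (764 higher and 854 lower in number 3) and 1418 between numbers 3 and 2 (677 higher and 741 lower). Between numbers 2 and 1 the count was 0 by limma, with 206 genes at an unadjusted p under 0.05. In the same direction against both, 1242 genes differed, 566 higher and 676 lower, and 67 of them at least 2-fold. Lower on the arrays numbered 3 than on those numbered 1 were the chemokine gene CXCL8 by a log2 difference of -3.90 (SE 1.03, adjusted p = 0.0185), the replication genes CDC45 by -2.04 (SE 0.258, adjusted p = 0.000286), RRM2 by -1.93 (SE 0.297, adjusted p = 0.000817) and MCM7 by -1.58 (SE 0.30, adjusted p = 0.003). Higher were the histone gene H2BC5 by 2.13 (SE 0.261, adjusted p = 0.000221) and the cyclin genes CCNG2 by 1.49 (SE 0.135, adjusted p = 4.21e-05) and CCNG1 by 1.15 (SE 0.101, adjusted p = 4.18e-05). All 7 showed that direction in 6 of 6 tumours, and they were chosen after their values were seen. Of the 24 lists, 13 had scores that differed by replicate number (exact permutation within tumours). The cell cycle score was lower on the arrays numbered 3 with 18 of 27 members lower (adjusted p = 0.0111), the inflammatory score with 6 of 19 members lower (0.0111), and the interferon score was higher with 8 of 21 members higher (0.0141). The platinum transport score was higher than on the arrays numbered 1 by 0.174 in 6 of 6 tumours (0.0111), with 3 of 13 members higher. The mesothelial score also differed by number (0.0111), but there the arrays numbered 1 stood apart, with numbers 2 and 3 lower than number 1 by 0.173 and 0.217, and 0 of 7 members differed on the arrays numbered 3 from both other numbers. Also under the threshold were the mismatch repair (0.0111), recombination (0.0129), metallothionein (0.0262), hypoxia (0.0275), ribosomal (0.0278), epithelial (0.0327), heat shock (0.035) and excision repair (0.0408) scores. The p53 target score was higher by 0.372 in 5 of 6 tumours and did not pass (exact permutation, adjusted p = 0.08), with 4 of 13 members higher. The labels used here do not say what distinguishes the replicate numbers.

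**Figure D4:**
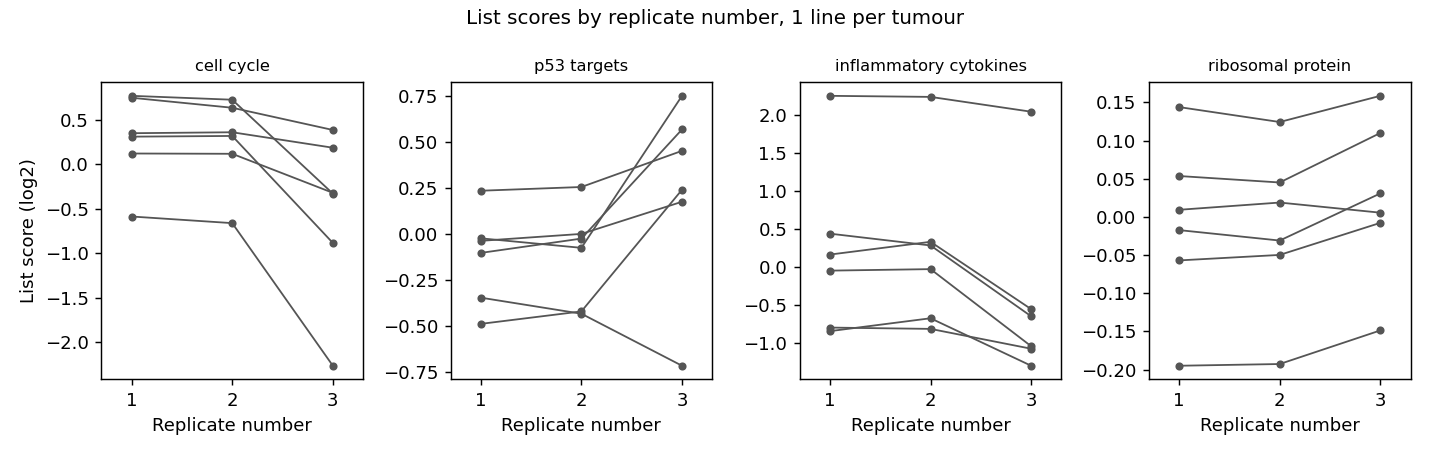
List scores (y axis, log2 units, separate scale in each panel) of the 18 arrays by replicate number (x axis) for 4 lists, with a line joining the 3 arrays of each tumour. The cell cycle and inflammatory scores are lowest at number 3 in 6 of 6 tumours, and the p53 target score is higher at number 3 than at number 1 in 5 of 6.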

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

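The tests of explanations below, except the random splits for differences among tumours, were chosen after the results had been seen. The inflammatory cytokine score was the list score in which 1 tumour lay far from the others: the gap between the highest tumour and the next took 0.691 of the whole range of 3.11 log2 units. Of 24 lists tested in this way, chance alone marks about 1 in 20. The 5 remaining tumours lay between -0.93 and 0.03. Without the arrays numbered 3 its range was 3.04 (adjusted p = 0.00144 by permutation test).

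Differences among tumours were set against random assignments of the 18 arrays to 6 sets of 3. Of 100 assignments, the real one included, only 1, the real one, gave 5771 differing genes, and the highest other count was 192. The same held for genes differing at least 2-fold, with 3341 against at most 171, again 1 of 100, and for the median over pairs of tumours, with 1189 against at most 6, again 1 of 100. Chance assignment of the arrays can therefore be excluded for these 3 counts. That shows only that replicate arrays of 1 tumour lie closer together than arrays of different tumours. It does not set tumours against a biological spread, because the labels leave open what the replicates are.

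The arrays numbered 3 had lower cell cycle and cytokine scores and higher interferon scores than the arrays numbered 1 and 2 of the same tumours. When the numbers were assigned at random within tumours, 1 of 100 assignments, the real one, gave as many as 1618 genes, and the highest other count was 365. Lower RNA integrity could lie behind such a split, but the log2 ratio of 3' to 5' control probe sets of GAPDH and ACTB differed by 0.00247 (standard error 0.0272) between number 3 and the other arrays, higher in 3 of 6 tumours, far from the 0.3 that was asked for. Hybridisation of spiked control RNA differed by -0.112 (standard error 0.0545), lower in 6 of 6 tumours but under the 0.5 that was asked for. A separate culture, RNA preparation, day or treatment for the arrays numbered 3 stays open, since no label used here describes the numbers, and no biological explanation was tested.

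The epithelial score tended to be lower where the matrix score was higher, which did not pass the exact test (r = -0.88, adjusted p = 0.063 over 6 tumours; -0.78 with the median of the members, adjusted p = 0.196). Leukocytes, endothelial cells or whole stroma in the samples could raise matrix genes. The larger of the leukocyte and endothelial score ranges was 0.0561 of the matrix range, below the tenth that was asked for, but this does not exclude them. Of the 29 members of both lists, 22 lay above 42.9 units even in the lowest tumour. That baseline could hide a small share of such cells. Another 4 stayed below 42.9 units even in the highest tumour. They gave no sign of such cells, but readings this low are uncertain. Only 3 lay below 42.9 units in the lowest tumour and above it in the highest, so they were picked by having risen. That these members were too few to decide was judged after their values were seen. The leukocyte score tended to be higher with the matrix score, but this did not pass (r = 0.93, adjusted p = 0.063; r = 0.69 without 2 tumours; 0.73 with the median of the members, adjusted p = 0.196), nor did the leukocyte score range itself (0.165, adjusted p = 0.133). Of the 3 members, CD68 differed at least 2.84-fold, CD163 about 1.57-fold (its other probe set correlated at 0.23) and LYZ about 1.10-fold (adjusted p = 0.82 by limma). CD68 may carry much of the leukocyte score, since its range was 3.27 log2 units and the next largest in that list was 0.842. The explanation stays open, since the test could not exclude it. A common dilution of epithelial cells by 1 other cell type remains possible too: the 16 epithelial genes with a range of at least 1 log2 unit correlated with each other at 0.509 on average over the tumour means, between the 0.7 expected of dilution and the 0.5 that would count against it. Fibroblasts without other stromal cells and carcinoma cells that express matrix genes cannot be told apart here, because bulk intensities do not show which cells held the RNA. No label gives a group that would test a biological explanation.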

How the results depend on the processing

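Leaving out the arrays numbered 3 or a whole tumour was chosen after the data were examined, and the other settings before. The counts of differing genes stayed within 1.5 times their values under every setting except the restriction to genes above the median by mean, where fewer genes were tested (3225 differing, 1608 at least 2-fold, median of pairs 521). There the within-tumour correlation was 0.951 and the between-tumour correlation 0.724. The median share of variance between tumours was 66.9% and moved to 64.8% with the floor at the 20th percentile, 72.8% above the median by mean, 75.4% with the replicate block, 86.2% without the arrays numbered 3, and 64.1% and 65.6% without 1 or another tumour (tumours 1 and 6). With 1 array left out it ran from 65.9% to 69.2%, the counts from 5524 to 5761, 3304 to 3406 and 1161 to 1202, and the lists that passed from 18 to 20. With 1 tumour left out, the lists that passed ran from 13 to 20. The 13 came without tumour 1. There the adipocyte, cell cycle, excision repair, recombination, mismatch repair and inflammatory cytokine calls were lost together, so these losses rest on 1 patient. The correlation of metallothionein with glutathione scores, 0.0053, turned to -0.0457 with the median of the members and to -0.0164 with values as deposited, and was -0.99 over the 4 tumours left without the 2 farthest from the median. Deviations of same-numbered arrays of different tumours correlated between 0.026 and 0.54 (median 0.242, against -0.199 for different numbers). Arrays numbered 3 correlated between 0.219 and 0.542, and the values under 0.1 came from numbers 1 and 2 (lowest 0.049 and 0.026). Not every pair passed 0.1, so by the rule used the numbers were not treated as pairing the samples, although 15 of 18 arrays correlated best with their own number. The replicate block gave 3422 genes at least 2-fold, of which 3336 were among the 3341, and brought the p53 target score (adjusted p = 0.0143) and the interferon score (0.000918) under the threshold. Of 127 named genes, 110 passed, and CD163, HBB (other probe sets correlated at 0.23 and 0.19) and PCNA lost the call with some array left out. The calls of 1 to 6 named genes changed under 5 of the settings, most with the mean of all probe sets. The cause of these changes was not tested. Signal over background limits genes read below 42.9 units.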

Other observations

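The gene lists in this part were drawn up after the data were examined, from families seen among the genes with the largest range, so their tests are not independent evidence. Genes of the smooth muscle contractile apparatus differed in 13 of 14 cases, 12 at least 2-fold, with a score range of 3.84 log2 units and 1 tumour at 2.70 against 0.57 in the next. TPM2, a tropomyosin, reached 5030 ± 446 units (about 106-fold), TAGLN, an actin-binding protein, differed 22.7-fold and ACTG2, the enteric smooth muscle actin, at least 15.1-fold, while MYH11, the smooth muscle myosin heavy chain, read 61.9 ± 2.99 to 70.3 ± 6.90 units (1.13-fold, adjusted p = 0.914 by limma) by a probe set with which another correlated at -0.68. Basement membrane genes differed in 16 of 17 cases, 15 at least 2-fold (score range 1.90), among them COL4A1 (at least 42.6-fold), COL4A2 (28.3-fold), LAMB1 (about 23.4-fold) and LAMC1 (6.76-fold). Of 9 claudin and tight junction genes, 7 differed, and CLDN7 did so at least 19.5-fold while OCLN, occludin, differed 1.36-fold. Of 7 genes of insulin-like growth factor binding proteins, 6 differed, each at least 2-fold: IGFBP7 about 77.5-fold, IGFBP4 at least 61.6-fold, IGFBP6 about 54.3-fold and IGFBP3 21.8-fold, while IGFBP5 read 280 ± 55.8 to 332 ± 12.9 units (adjusted p = 0.355 by limma; another probe set correlated at -0.50).

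Of 14 keratin genes, 9 differed and 6 did so at least 2-fold (KRT18 66.9-fold, KRT7 about 25.3-fold, with another probe set of KRT7 correlating at 0.45), whereas KRT14 differed 1.26-fold and did not pass (adjusted p = 0.169 by limma). Of 16 matrix metalloproteinase and inhibitor genes, 13 differed, with MMP1 about 29.3-fold and the inhibitor TIMP1 11.3-fold (713 ± 39.2 to 8098 ± 727 units). Of 14 S100 genes 12 differed, S100A2 by 8.97-fold and S100A10 by 2.95-fold, and of 17 integrin genes 13 differed, ITGA5 by 15.5-fold and ITGB1 by 2.78-fold, with another probe set of ITGB1 correlating at -0.12. HOXB2, a homeobox gene, differed at least 21.1-fold, while of the 7 measured genes of the HOXA and HOXB clusters 4 differed and 1 did so at least 2-fold. Of 17 glycolytic genes, 15 differed (16 adjusted over the list alone) and 8 did so at least 2-fold. LDHB differed at least 73.8-fold and FBP1, a gluconeogenic phosphatase, at least 38.7-fold, whereas LDHA differed 1.98-fold and PGK1 1.48-fold. The scores of all 10 lists passed the permutation test (adjusted p between 1.43e-05 and 0.00016). Since 71.0% of all genes differed and the families were picked for wide ranges, that says little about a family. The members' median SD between tumours was higher than in 11.4% of random lists of like expression for HOXA and HOXB and 15.3% for keratins. For metalloproteinases and claudins it was 66.3% and 67.4%. For S100, glycolytic and integrin genes it was 90.6% to 93.4%, and for the other lists 100%.

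Among the 3341 genes that differed at least 2-fold, the widest gap between neighbouring tumour means parted 1 tumour from 5 below it in 928 genes (27.8%, against 28.0% in draws from a normal distribution) and from 5 above it in 763 (22.8%, against 27.8%). It parted the 2 highest tumours from the others in 687 genes (20.6%, against 15.4%) and the 2 lowest in 515 (15.4%, against 15.5%). Of the 1119 probe sets with no gene, 49 control probe sets were left out, and of the other 1070, 609 (56.9%) differed among tumours and 326 did so at least 2-fold.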
